A study of Mus musculus with 8 samples.

How the data were processed

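The 8 libraries held shRNA inserts amplified from genomic DNA of mouse cells carrying a pooled shRNA library from Open Biosystems, with 1 library before and 1 after hygromycin B in each of 4 screens. Per the labels, DNA was extracted and sequenced after an Illumina TruSeq DNA preparation, and the genome build named was mm10. The aligner or counting program is not stated. The deposited table holds a read count for each 19-base shRNA and library. Its unit was handled as an expected or estimated count, because the 7 lines that the authors placed under the table include values that are not whole numbers. The counts of the shRNAs themselves were all whole, so that rounding changed nothing.

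The table lists 49920 pairs of a gene symbol and a sequence. These hold 38925 distinct sequences and 23089 symbols, and 4211 sequences are listed for more than 1 symbol, up to 36, with the same counts each time. Each sequence was therefore used once in the shRNA test. Symbols with exactly the same shRNAs were joined into 1 gene entry, which gave 19576 entries, 13005 of them with at least 2 shRNAs and 6571 with 1. An shRNA listed for several entries counted in each. There were 4125 sequences with 0 counts in all 8 libraries, and 20 symbols had the form of spreadsheet dates and were kept as listed. The 7 lines without a gene or sequence were left out. They hold column totals, which equal the sums over all listed lines in 8 of 8 libraries, and values for the Xist shRNAs, 25 of 32 of which lie within 0.1% of the counts scaled to a common library size. Gene coordinates came from the RefSeq annotation of mm10, in which 14325 symbols are current and 3935 further symbols matched 1 synonym. Positions of the shRNA targets were not analysed here, since no genome sequence was at hand.

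Samples were grouped by their labels into preHYG (n = 4) and postHYG (n = 4). Total counts ranged from 8015029 to 19106658 per library, summed over distinct sequences. Intervals of shares cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The screen number in the labels pairs the libraries. As a check, the deviations of the 2 libraries of a screen from their group means were correlated across shRNAs, which gave 0.149, 0.0512, 0.0227 and −0.0273 in screens 1 to 4. The screen entered as a block in an alternative, and its value stands beside a result where it changes a call. The nearly identical preHYG libraries of screens 3 and 4 were kept as 2 samples and summed in an alternative.

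ShRNAs, and separately the sums of the shRNAs of each gene entry, were tested after against before hygromycin with edgeR 4.0.16 (quasi-likelihood F test with robust dispersions, group as the only term). Library sizes were scaled with TMM, and items with at least 10 counts in at least 2 of the 8 libraries were kept, which left 33732 shRNAs and 18484 genes. The p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The common dispersion was 2.03 for shRNAs and 1.36 for genes. Fold changes are given on the log2 scale. Their standard errors were derived from the test, as the absolute fold change divided by the square root of the F statistic. The median fold change of all genes was −0.12 with TMM, 0.14 with DESeq2's size factors and −0.86 with total counts alone, so that the sign of a small change depends on the scaling. Ratios of single screens are log2 of CPM after to before with a pseudocount of 1 CPM, on total counts. A gene or shRNA is called higher or lower in a screen where its ratio lies above or below 0. The median ratio of all tested genes was itself −0.20, −0.07, −1.87 and −1.59 in screens 1 to 4.

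The 15 gene lists were written before the data were examined and tested with camera of limma 3.58.1 on voom values of the gene sums, with a preset correlation between genes of 0.01 and again with the correlation estimated, adjusted over the 15 lists. The factors of the earlier fibroblast screen were listed from general knowledge of that screen, not from these samples. Genes with at least 2 shRNAs that each reached a log2 ratio of 2 in at least 2 screens were counted and compared with 10000 random reassignments of shRNAs to genes that keep the number per gene (2000 for the alternatives). Library complexity was compared by exact permutation over the 70 assignments of the libraries, and screens by Pearson and Spearman correlation over 6 pairs.

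The genes to name were fixed in advance. In the shRNA and gene tests these were up to 12 and 15 items past the threshold that were higher in 4 of 4 screens and 5 that were lower, by p, and where fewer passed, the next 5 in each direction as values that did not pass. Further names were the 10 genes with the most pairs of an shRNA and a screen over the limit, the members of each list past the threshold or else the one with the smallest p, the most abundant shRNA after hygromycin in each screen, and Mecp2, Xist, Acvr1, Bmpr2, Smad4, Rlim and Dnmt1. Any other name is said to be chosen after its values were seen.

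Alternatives covered the scaling (DESeq2's size factors, total counts alone), the count filter (none, filterByExpr), the tool (DESeq2 1.42.0, limma-voom), the screen as a block, each screen and each library left out, gene sums without the most abundant shRNA, fry over the shRNAs of a gene, list tests on shRNA values, other limits and pseudocounts, and libraries thinned to the smallest total. A GC offset was added after the data were examined: within each library, the mean log2 CPM of each of 11 GC classes (3 or fewer to 13 or more G and C bases), relative to the library mean and to the mean over libraries. Also added then were the GC offset with the block, list tests with the block and an estimated correlation, fits with screens 1 and 2 only, without the postHYG libraries of screens 3 and 4, and with screens merged in the count over shRNAs. The software was R 4.3.3 and Python 3.11.15.

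The shRNA, gene and list tests were tested on simulated counts with the dispersion of the real ones, and the count over shRNAs on shuffled values. The complexity tests and the correlations between screens were not simulated. Of 50 shRNAs planted at each size, the shRNA test recovered 0 at 4-fold, 3 at 16-fold and 23 at 64-fold, and called 7 of 32223 unchanged ones. The gene test recovered 6 of 40 planted at 16-fold. The list test called the planted list and 0 of 20 others. The simulated shRNAs were drawn independently, whereas the estimated correlation between genes was 0.16 in the real ribosomal list. It was 0.105 in the proteasome list and 0.29 in that of the earlier fibroblast screen. The simulation therefore cannot show that false list calls are controlled in the real data. In the count over shRNAs on shuffled values, 30 planted genes gave a permutation p of 0.0699 and 60 gave 0.00798.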

Results

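The series followed a pooled short hairpin RNA (shRNA) library through 4 screens in mouse cells in which the copy of Mecp2 on the silent X chromosome was joined to a gene for resistance to hygromycin, an antibiotic that blocks protein synthesis. Each screen gave 1 library of shRNA inserts from genomic DNA before the drug and 1 after it, which makes 4 libraries per group and 8 in all. The counts per library were 19106658, 8749254, 11048932 and 12274406 before hygromycin in screens 1 to 4. After hygromycin they were 10792395, 11136003, 8015029 and 10776848. The table lists 38925 distinct shRNAs of 19 bases. The preHYG libraries of screens 3 and 4 were close to copies of each other (Pearson r = 0.99 across shRNAs), which no other pair of libraries before the drug was. Their differences were 4.38 times what counting error alone gives, as a chi-square per degree of freedom, against 174 to 378 for the other pairs. Nothing in the labels says that the 4 screens came from separate cultures, so p-values measure the spread between samples only. Because of the near-copies, an SD or a count over 4 screens does not rest on 4 independent values.

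The first comparison asked how far the pool narrowed from before to after hygromycin. After hygromycin a few shRNAs held more of each library, in all 4 screens. The most abundant shRNA in screens 1 and 4 targeted Xist, the long noncoding RNA that coats and silences the inactive X chromosome. This shRNA, CCAACTGTCTGCTTAAGAA, made up 2.48% of the counts of screen 1 (95% Wilson interval 2.47% to 2.49%), against 0.123% before the drug. In screen 4 it made up 1.61% (1.60% to 1.61%), against 0.00631% before. In screen 2 the most abundant shRNA was CCGGGAATGAATATCTTAT, against the kinase gene Pdpk1, with 1.26% (1.26% to 1.27%), and in screen 3 it was GGTATTCTAGATAATATTA, against the secretoglobin gene Scgb2a2, with 2.88% (2.87% to 2.89%). These had held 0.220% and 0.0487% before the drug.

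The 10 most abundant shRNAs together held 7.85% ± 2.49 of the counts after hygromycin (SD, n = 4) and 2.36% ± 2.49 before it. The difference of 5.49 percentage points gave p = 0.0571 in a two-sided exact permutation test, in which 0.0286 is the smallest possible. The share of listed shRNAs with at least 1 count was 67.3% ± 5.48 after and 80.4% ± 9.81 before (p = 0.0857, same exact permutation test). The effective number of shRNAs, the exponential of the Shannon entropy, was 5569 ± 2078 after and 17288 ± 10027 before (p = 0.0571, exact permutation test). All 3 measures moved the same way in 4 of 4 screens, and none passed the test. An exact sign-flip test within the screens gave 2 of 16 sign patterns, the smallest share it can give. The libraries before the drug already differed: the effective number was 7253 and 10071 in screens 1 and 2 and 25769 and 26057 in screens 3 and 4.

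The main comparison asked which shRNAs gained or lost share from before to after hygromycin. No culture kept without the drug is among the samples. Survival of the drug therefore cannot be told apart from growth or loss over time in culture. The 4 shRNAs against Xist (X chromosome, 103460373 to 103483233, mm10) rose together in screens 1, 3 and 4, though single shRNAs of other genes rose further. Their log2 ratios after to before, from counts scaled to library size (CPM), lay between 3.44 and 5.05 in screen 1, between 4.21 and 6.26 in screen 3 and between 5.996 and 7.97 in screen 4. In screen 2 they lay between −1.71 and 2.19, with 2 of the 4 below 0. Other shRNAs that were higher after the drug in 4 of 4 screens were GACACAGACAGCCCTAATA against Rab38, a GTPase of melanosome transport (7, 88430273 to 88491572), and CAGCACTCCCGATTCATAA against Acaca, the acetyl-CoA carboxylase that makes malonyl-CoA for fatty acid synthesis (11, 84129635 to 84401651). ShRNAs lower in 4 of 4 screens included CACTGGCCCTGGTGGAAGA against 2310079N02Rik and CAAAGAATTGCGTGTGTTT against Ell2, an RNA polymerase II elongation factor (13, 75707484 to 75772361).

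**Figure D1:**
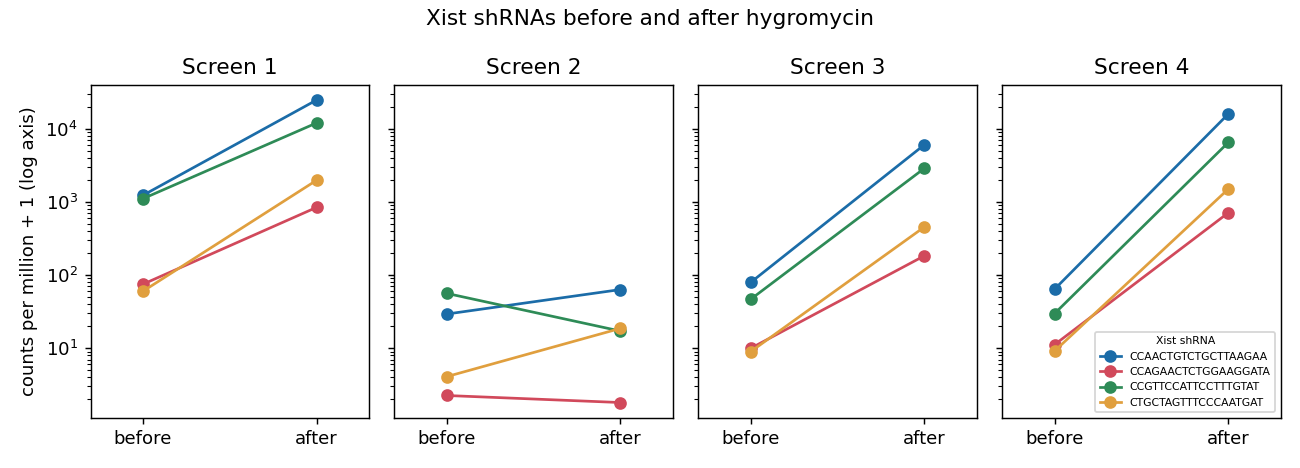
CPM plus 1 (log axis) of the 4 Xist shRNAs before and after hygromycin, with 1 panel per screen, 1 line per shRNA and 1 library per point. The log2 ratios lie between 3.44 and 7.97 in screens 1, 3 and 4, and between −1.71 and 2.19 in screen 2.

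Of 33732 shRNAs tested with edgeR's quasi-likelihood test, none passed an adjusted p of 0.05 in either direction. At an unadjusted p under 0.05 there were 4745, of which 1335 were higher after hygromycin and 3410 lower, on a scale where the median shRNA had a log2 fold change of −0.36. With total counts alone this median was −1.19 and with DESeq2's size factors 0.20. On the same counts DESeq2 called 547 shRNAs higher and 678 lower, and limma-voom 31 higher and 160 lower. With the screen as a block edgeR still called 0 and 0, and with the block and an offset for the GC content of the shRNA, added after seeing the data, it called 47 higher and 4 lower. Summing the near-copies before the drug in screens 3 and 4 to 1 library left 2290 of 31332 shRNAs at an unadjusted p under 0.05. Leaving 1 of them out left 2301 or 2304, while leaving out the screen 1 or 2 library before the drug left 5407 or 4572. The 4745 therefore rest in part on counting near-copies as 2 samples.

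The smallest adjusted p was that of the Rab38 shRNA, 0.0686, at a log2 fold change of 6.85 ± 1.29 (SE, n = 4 libraries per group). Among shRNAs higher in 4 of 4 screens, which the naming rule required, the Acaca shRNA came next by p with 5.51 ± 1.14 (adjusted p = 0.128). Then came GATTTCTCCTCTTAGCTAA against Ttn, the giant protein of the sarcomere, with 4.90 ± 1.07 (adjusted p = 0.177). CCATTACCGTGTATTAAAT against the noncoding RNA Dnm3os gave 5.88 ± 1.33 and CACAAATGTGCAATTGTCA against Smn1, the survival motor neuron gene, 4.93 ± 1.13, both with an adjusted p of 0.177. The same value belonged to shRNAs named from those lower in 4 of 4 screens, at −7.72 ± 1.71 for 2310079N02Rik, −7.33 ± 1.73 for Ell2 and −6.20 ± 1.43 for CCATCTAAACTTGACATGA against Klra10, a natural killer cell receptor. The Klra10 shRNA is listed for 5 symbols. The shRNA CTGTGGAGATCATCTTCAA against Pccb, a subunit of propionyl-CoA carboxylase, had 113 to 1249 counts before hygromycin and 0 to 2 after it, and CCCAGAGCACTGTGATTCA against BC050092 gave −7.79 ± 1.99 (adjusted p = 0.215). Among the Xist shRNAs, CTGCTAGTTTCCCAATGAT reached 6.09 ± 1.45 (adjusted p = 0.192) and was higher in 4 of 4 screens; the other three had fold changes of 4.43 to 5.40 and an adjusted p of 0.282. With the GC offset and the screen block, 3 of the 4 Xist shRNAs passed, with adjusted p values of 8.2e-05, 0.0122 and 0.0191.

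Some shRNAs were abundant after hygromycin in screen 1 but rare before it in screens 3 and 4. These were found after it in screens 3 and 4 more often than in screen 2, a set chosen after the result was seen. Abundant shRNAs in general were found in every screen. Of 549 with at least 1000 counts after hygromycin and no gain in screen 1, 95.4% reached 0.1 times their screen 1 share after it in screen 2. In screens 3 and 4 it was 97.45% and 100%. Of 236 shRNAs with at least 1000 counts after hygromycin in screen 1 and under 0.1 times that share before it in screens 3 and 4, 99.6% reached 0.1 times the screen 1 share after hygromycin in screen 4 (95% exact interval 97.7% to 100%) and 89.8% in screen 3 (85.2% to 93.4%). In screen 2 it was 41.1% (34.8% to 47.7%). Starting from 236 such shRNAs of screen 4, 91.9% were found in screen 1, 70.3% in screen 3 and 33.9% in screen 2. Those abundant in screen 3, again 236, were not shared in this way, with 41.1% in screen 1, 46.2% in screen 4 and 32.2% in screen 2. The Xist shRNAs were among those of screen 1, at 0.217 to 0.245 of their screen 1 share in screen 3 and at 0.543 to 0.845 in screen 4.

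Summed over the shRNAs of each gene, no single gene passed either. Xist had a log2 fold change of 5.07 ± 2.14 (SE, n = 4 per group; adjusted p = 0.350) and ratios of 4.01, 0.14, 6.08 and 7.80 in screens 1 to 4. Bmpr2, a type II receptor for bone morphogenetic proteins (BMP), gave 2.52 ± 0.92 (adjusted p = 0.328) from 1 shRNA, since the other shRNA had 0 counts in all 8 libraries; its ratios were 1.84, −2.91, 1.61 and 3.78. Acvr1, a type I BMP receptor, gave 0.63 ± 0.91, with ratios of −0.64, −1.06, 0.69 and 2.39, and its log2 fold change without screen 4 was −0.03. Dnmt1, the maintenance DNA methyltransferase, gave 1.02 ± 1.21, with ratios of −0.14, −1.63, 2.62 and 4.13. Its log2 fold change without the screen 1 library before the drug was 3.54. Of its 2 shRNAs, 1 had ratios of −0.12, −1.47, 3.57 and 5.30. The other lay below 0 in every screen, at −1.88, −4.745, −0.52 and −0.07. The Dnmt1 ratios above 0 in screens 3 and 4 therefore rest on 1 shRNA. Rnf12 (now Rlim), a ubiquitin ligase that activates Xist, gave 0.63 ± 0.62 with TMM scaling, while its ratios, on total counts, were −0.14, 0.92, −2.01 and 0.25, with a mean of −0.24. Mecp2 itself gave 0.22 ± 1.02 with TMM scaling, −0.29 with total counts alone and −0.79 with the screen as a block. Without the screen 2 library after hygromycin it gave −1.92, and without the screen 1 library before the drug −0.14. Its ratios were −0.80, 0.81, −3.74 and −1.94, below 0 in 3 of 4 screens. On the same scale the median ratio of all tested genes was −0.20, −0.07, −1.87 and −1.59, so ratios below 0 were usual in screens 3 and 4. Smad4, the common partner of the receptor-regulated Smads, has no entry under that symbol and was not analysed here.

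Of 18484 genes tested, edgeR called 0 higher and 0 lower, with 2286 at an unadjusted p under 0.05. DESeq2 called 365 higher and 274 lower, and limma-voom 0. With the screen as a block edgeR called 8 higher and 5 lower. Among these were Rpl11, a protein of the large ribosomal subunit (4, 136049354 to 136053393), at −4.89 (adjusted p = 0.00504), and Smn1 at 3.73 (adjusted p = 0.0358). The gene called with the smallest adjusted p was Fbxo32, a muscle ubiquitin ligase named here because it was seen to lead, at 4.65 (adjusted p = 0.0011). Without the screen 2 library after hygromycin the unblocked test called 13 higher and 5 lower. With the near-copies before the drug in screens 3 and 4 summed to 1 library, 1237 of 17837 genes had an unadjusted p under 0.05.

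In the unblocked test the lowest gene by p was Rpl11 at −5.33 ± 0.89 (adjusted p = 0.142), lower in 4 of 4 screens, though both its shRNAs are also listed for other genes. The other genes named here were also picked by p among those lower in 4 of 4 screens. Nphp4, a ciliary transition zone gene, gave −8.12 ± 1.66, the noncoding RNA 4933413J09Rik −5.23 ± 1.13 and Pla2g5, a secreted phospholipase, −6.76 ± 1.57, with adjusted p values of 0.280 to 0.288. Pccb had a single shRNA, described above. Among genes higher in 4 of 4 screens, which the naming rule required, the 5 with the smallest p all had an adjusted p of 0.280. They were Mbd3l1, a methyl-CpG-binding protein relative, at 3.66 ± 0.76, D030059C06Rik at 2.99 ± 0.62, Gm821 at 4.08 ± 0.86, Smn1 at 4.20 ± 0.91 and Gm1600 at 3.22 ± 0.71. Mbd3l1 and Gm821 had 1 shRNA each.

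Gene lists fixed in advance asked which cellular functions the knockdowns touched. Those of the core machinery of growth were lower after hygromycin, where effects of the drug and of time in culture cannot be told apart. Against all other genes, shRNAs to ribosomal proteins fell (58 genes, camera adjusted p = 4.8e-05), as did those to the subunits of the proteasome, which degrades proteins (21 genes, adjusted p = 4.8e-05), and those to the spliceosome and RNA polymerase II core (27 genes, adjusted p = 0.00555). With an estimated correlation the adjusted p was 0.627 for ribosomal proteins and 0.222 for each of the other lists, so none of these calls held. The median log2 ratio of the ribosomal genes was below that of all genes by 0.97 ± 0.45 on average (SD, n = 4 screens), that of the proteasome genes by 1.44 ± 1.06 and that of the third list by 0.92 ± 0.62, each below in 4 of 4 screens, where an exact sign-flip test cannot go under 2 of 16 patterns. The 4 screens are not 4 independent values here, since the libraries before the drug in screens 3 and 4 were near-copies (Pearson r = 0.99). Those after it in screens 1 and 4 had an r of 0.784. Of the proteasome genes 20 of 21 had a fold change below 0. Over all genes tested edgeR called 0 of the 106 members of the 3 lists, with 24 at an unadjusted p under 0.05, and adjusted over the list alone Rpl11 passed (adjusted p = 0.000445). Over all genes DESeq2 called 9 members lower, limma-voom 0 and fry 1, and with the screen as a block edgeR called 2 lower. Psmb7, a catalytic proteasome subunit, gave −5.29 ± 1.88 and Snrpe, an Sm core protein, −6.84 ± 1.96, neither past the threshold over the list alone. Both Psmb7 shRNAs and 1 of the 2 Snrpe shRNAs are also listed for other symbols. With screens 1 and 2 only, added after seeing the data, the spliceosome list had an adjusted p of 0.0731.

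**Figure D2:**
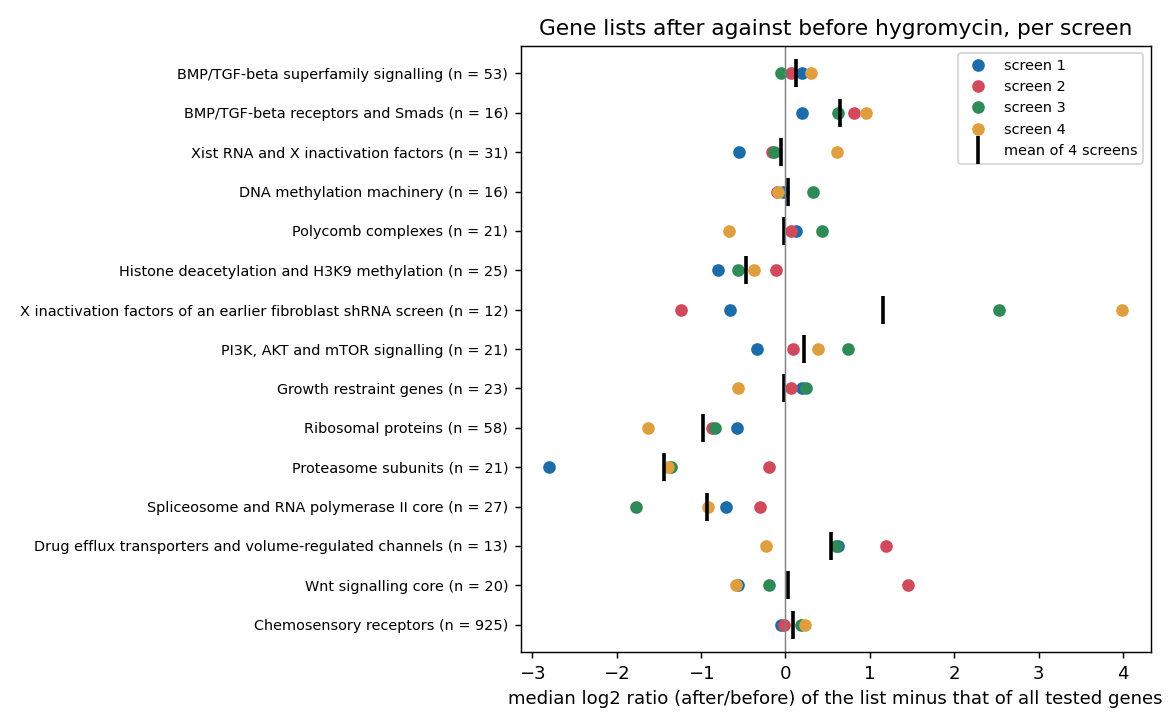
Median log2 ratio (after to before hygromycin) of each gene list minus that of all 18484 tested genes, with 1 coloured point per screen and a black bar at the mean of the 4 screens. The ribosomal, proteasome and spliceosome lists and that of histone deacetylation and H3K9 methylation lie below 0 in 4 of 4 screens. The list from an earlier fibroblast screen lies below 0 in screens 1 and 2 and above it in screens 3 and 4.

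The BMP and TGF-β lists address the pathway in the series title. Genes for its receptors and Smads lay above all genes in 4 of 4 screens, by 0.65 ± 0.33 in the median log2 ratio (SD, n = 4 screens). With near-copies before the drug in screens 3 and 4, these are not 4 independent values. The 16 genes had a camera adjusted p of 0.431, and of 0.0371 with the screen as a block. With an estimated correlation the adjusted p was 0.629, and 0.281 with the block, so that call did not hold. The member with the smallest p was Smad2, a TGF-β signal transducer, at 2.97 ± 0.97, with ratios of 3.90, −1.54, 1.26 and 1.58; over the list alone its adjusted p was 0.101. Of the 16 genes, 3 had an unadjusted p under 0.05 and a higher value after the drug, and none a lower one. The wider superfamily list of 53 genes, ligands and antagonists included, gave an adjusted p of 0.813.

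A list of 12 X inactivation factors known from an earlier fibroblast shRNA screen had the most uneven values. It rose against all other genes (camera adjusted p = 0.0316), with an adjusted p of 0.677 with an estimated correlation. Its median log2 ratio lay below that of all genes by 0.65 in screen 1 and by 1.23 in screen 2, and above it by 2.53 in screen 3 and 3.98 in screen 4. With screens 1 and 2 only, added after seeing the data, it was lower (adjusted p = 0.00225), and the adjusted p was 0.453 without screen 3 and 0.515 without screen 4. Stc1, a secreted glycoprotein hormone, had the smallest p of its members (2.001 ± 0.680, adjusted over the list alone 0.0981). A few shRNAs of this list were abundant before hygromycin in screen 1: 6 of 28 stood at least 5-fold above screen 3, among them the Dnmt1 shRNA CCTTTACTTTCAACATCAA with 2099 CPM against 46.2. Of the 28, 11 had under 10 CPM, as did most shRNAs of that library, whose median was 37 counts of 19106658.

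The other lists passed in neither direction. Camera adjusted p values were 0.765 for Xist and X inactivation factors, 0.987 for DNA methylation, 0.850 for Polycomb, 0.571 for histone deacetylation and H3K9 methylation, 0.987 for PI3K, AKT and mTOR signalling, 0.813 for growth restraint genes, 0.571 for drug efflux and 0.765 for Wnt signalling. A list of 925 chemosensory receptors, with no function foreseen in cultured cells, gave 0.813. The histone deacetylation and H3K9 methylation list, like those of the core machinery, lay below all genes in 4 of 4 screens. Its mean difference in the median log2 ratio was −0.46 ± 0.29 (SD, n = 4 screens). Across the 12 lists outside the core machinery edgeR called 1 gene adjusted over the list alone and 0 over all genes tested, with 136 of 1152 at an unadjusted p under 0.05. Over all genes DESeq2 called 20 higher and 15 lower, limma-voom 0 and fry 2 lower. The gene called over the list alone was Pik3cb, a catalytic subunit of PI3K, at 2.57 ± 0.69 (adjusted over the list alone 0.0272, over all genes 0.288), higher in 4 of 4 screens; without its most abundant shRNA its log2 fold change was −0.26. The members with the smallest p elsewhere were Lbr, the lamin B receptor, at 2.24 ± 0.84, Mbd4, a methyl-CpG-binding glycosylase, at −6.07 ± 2.16, the Polycomb-like gene Mtf2 at 1.71 ± 0.60, the transporter gene Abcc5 at 1.94 ± 1.01, Gpr177 (now Wls), needed to secrete Wnt proteins, at 2.15 ± 0.86, and the odorant receptor gene Olfr870 at 3.85 ± 0.95. Both Olfr870 shRNAs are also listed for other symbols. Ehmt1, an H3K9 methyltransferase, and Cdkn2b, a cell cycle inhibitor, had 0 counts after hygromycin in 4 of 4 screens, and 0 counts before it in screens 1 and 2.

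The next comparison asked whether several shRNAs against the same gene gained share in several screens, which guards against shRNAs that hit the wrong gene. Xist led with 13 of 16 pairs of an shRNA and a screen at a log2 ratio of at least 2: 4 shRNAs in screen 1, 1 in screen 2 and 4 in each of screens 3 and 4. Eif1, a translation initiation factor, and Emd, the nuclear envelope protein emerin, had 10 pairs each, 638867 had 9 and 100042763 had 8, and these 4 entries share shRNAs that are listed for up to 21 symbols. Mobkl1a (now Mob1b), a Hippo pathway cofactor, had 9 pairs, Ttn 9, the immunoglobulin locus Igh 9, Ccdc46 (now Cep112) 7 and Akap13, a kinase anchoring protein, 7. Ttn, Igh and Akap13 had only 1 shRNA over the limit in at least 2 screens.

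In all, 72 genes had at least 2 shRNAs over the limit in at least 2 screens. Random reassignment of shRNAs to genes gave 76.5 on average, 95% of them between 58 and 100 (one-sided permutation p = 0.668), so the count did not exceed chance. In at least 3 screens there were 5 such genes, against 1.03 by chance (permutation p = 0.0125). The 5 entries were Xist, with all 4 of its shRNAs, and Eif1, Emd, 638867 and 100042763, which reached the count through the same 2 shRNAs each. With screens 1, 3 and 4 counted as 1 screen, added after seeing the data, there were 17 genes against 22.2 by chance (permutation p = 0.869).

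Last, the log2 ratios of the 38925 shRNAs were compared between screens, as correlations across shRNAs, which are not independent replicates. Screens 3 and 4 had a Pearson r of 0.449. Screens 1 and 4 gave 0.264, screens 1 and 3 0.105, screens 1 and 2 0.0244, screens 2 and 3 −0.0198 and screens 2 and 4 −0.0721. Among shRNAs with at least 10 counts before the drug in both screens, r was 0.384 for screens 3 and 4 and 0.388 for screens 1 and 4. Over all shRNAs, Spearman values were 0.452, 0.254, 0.114, 0.0230, −0.0173 and −0.0642 in the same order. Because the libraries before the drug in screens 3 and 4 were nearly the same, chance differences in them enter both ratios. Set against the screen 2 library before the drug, screen 4 had an r of 0.0970 with screen 3, of 0.389 with screen 2 and of 0.269 with screen 1. The libraries before the drug of screens 1 and 2, which saw no selection, gave an r of 0.439 to 0.443 with each other when set against those of screens 3 and 4, with a covariance of 1.76 to 1.78, against 1.99 for screens 3 and 4 themselves.

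Abundance also followed the base composition of the shRNA. From 5 to 10 G and C bases the mean log2 CPM dropped by 3.50 and 3.19 before hygromycin in screens 1 and 2, by 0.59 and 0.46 before it in screens 3 and 4, and by 2.40 to 3.12 after it in the 4 screens.

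**Figure D3:**
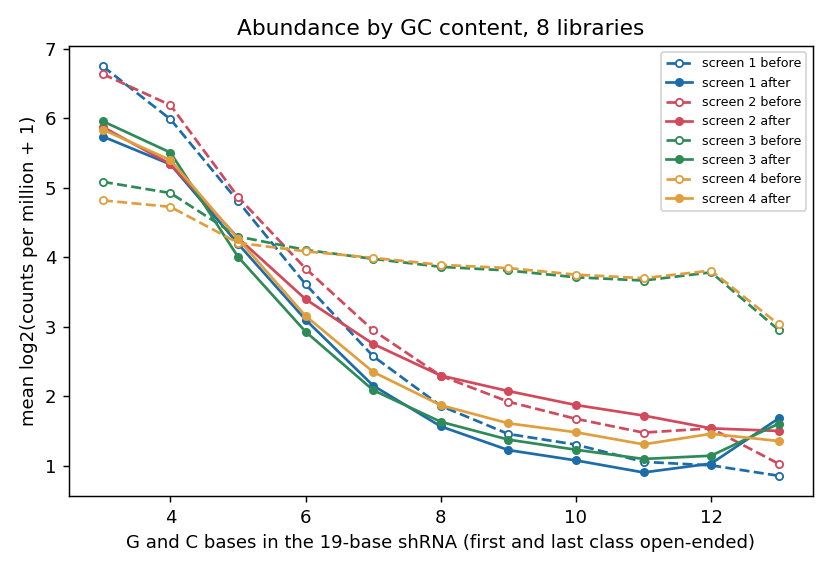
Mean log2 of CPM plus 1 by the number of G and C bases in the shRNA, with 1 line per library, dashed and open before hygromycin, solid and filled after it. The libraries before the drug in screens 3 and 4 are nearly flat, with drops of 0.59 and 0.46 from 5 to 10 bases, whereas the other 6 drop by 2.40 to 3.50.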

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

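The tests on shRNAs that were rare before hygromycin in screens 3 and 4, on the GC dependence before the drug, on Xist alone, and on the ratio of the Xist shRNAs to screen 1 were chosen after the result was seen. Of 79 groups of 4 values, 3 held 1 value far from the other three by Dixon's limit, where chance gives about 4.0. The total count after hygromycin was 8015000, to the nearest 1000, in screen 3, against 10777000 to 11136000 in the other screens. The log2 ratio of Mbd4 was −3.06 in screen 2, against −4.11 to −4.03. The log2 ratio of Gpr177 was 2.61 in screen 2, against −0.40 to 0.10.

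The shRNAs abundant after hygromycin in screen 1 were seen again after it in screens 3 and 4. Of 25 such shRNAs with no gain of share in screen 1 and little share after hygromycin in screen 2, 100% reached 0.1 times their screen 1 share in both screens 3 and 4. However, 84.0% did so before the drug in screen 4, so the test decided nothing for carried-over material or for the same selection in each screen. On the 236 shRNAs that were rare before hygromycin in screens 3 and 4, material of the screen 1 library or its cells may explain screen 4, where 99.6% reached that share against 41.1% in screen 2. In screen 3 the share was 89.8% (95% exact interval 85.2% to 93.4%), under the 90% set for this explanation but with 90% inside the interval, so it was not excluded there. Selection of the same knockdowns in separate cultures cannot be told apart from shared material on either set of shRNAs. Most of the 25 were present in the screens before the drug. Any of the 236 that reached that share after the drug in screen 4 had gained share there, which selection gives as well. Before the drug, 65.3% of the 236 reached it in screen 1 and 48.3% in screen 2, both above the 41.1% after the drug in screen 2. The labels do not say how the cultures were started.

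The share of an shRNA dropped with its GC content in all 8 libraries, by 0.46 and 0.59 in the libraries before the drug of screens 4 and 3 and by 2.40 to 3.50 in the other 6 (log2, from 5 to 10 G and C bases). Hygromycin selection as the cause was argued against by the drops of 3.50 and 3.19 before the drug in screens 1 and 2, which lay above the range of 2.40 to 3.12 after it. Taking GC content out lowered the covariance of screens 3 and 4 by 21.6%, from 1.99 to 1.56, which argues against a GC-dependent difference as the only cause of their agreement. A difference in amplification or sequencing may underlie the dependence itself, but the labels give no library batch, and no biological explanation other than selection was tested.

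All 4 Xist shRNAs had log2 ratios of 3.44 or more in screens 1, 3 and 4. Their GC content was argued against as the cause, since their median in screen 1 lay at percentile 99.87 of random sets with the same GC content, although in screen 2 it lay at 65.9. Outgrowth of single clones was argued against for Xist as a gene named in advance, with a chance of 0.0267% that 4 random shRNAs all reach the limit in screen 1, but over 1624 genes with at least 4 shRNAs 1 such gene against 0.283 by chance left it open (permutation p = 0.243, and 0.0013 and 0.0032 in screens 3 and 4). Material of the screen 1 library as the only cause in screens 3 and 4 stays open, because the share of the Xist shRNAs relative to screen 1 lay at percentiles 37.1 and 41.8 of 232 other shRNAs that were rare before the drug. That loss of Xist freed the silent resistance gene may be the biological reason, but no test here measured reactivation, and in screen 2 the median log2 ratio was 0.40.

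Other splits of the 8 libraries into 4 and 4 were run through the same models. The real split called 0 shRNAs and 0 genes by edgeR, with 4745 and 2286 at an unadjusted p under 0.05 (DESeq2 called 1225 and 639, limma-voom 191 and 0), so that 35 of 35 splits give as many by construction and these counts test nothing. The highest other split called 142 shRNAs and 83 genes. It groups the screen 1 library before the drug with the libraries after it in screens 1, 3 and 4, which points to a structure of the samples other than the drug. For the number of gene lists, 3 of 35 splits gave as many as the real 4 (highest other 4), so chance cannot be excluded. For ribosomal proteins 2 of 35 splits gave as small a p (6.4e-06, lowest other 1e-07), and for the earlier fibroblast screen 16 of 35 (0.00844, lowest other 2.4e-08), so chance cannot be excluded for either. For the proteasome only 1 of 35 splits, the real one, did so (4.95e-06, lowest other 0.000419), and likewise 1 of 35 for the spliceosome list (0.00111, lowest other 0.0115). The 4 lists compared singly were the 4 called in the real split, which favours that split, and 1 of 35 is the smallest share possible. These shares therefore do not exclude chance. They would also need 8 independent libraries, which the near-copies before the drug in screens 3 and 4 put in doubt. Both calls were lost in camera with an estimated correlation (adjusted p = 0.222 for each, the highest over their alternatives).

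Among the 7 other splits that part the libraries of all 4 screens, the highest counts were 51 shRNAs, 0 genes and 3 lists, and the lowest p was 3.7e-05 for ribosomal proteins, 0.000419 for the proteasome, 0.0233 for the spliceosome list and 9.1e-08 for the earlier screen. The real split had the lowest p of these 8 for the ribosomal, proteasome and spliceosome lists, but 8 are too few for a share under 0.05. Swaps within screens number 8, too few for a share under 0.05. With the GC offset and the screen block, 1 of 8 swaps called as many shRNAs as the real 51 (highest other 43, with screen 2 swapped), and with the block alone 2 of 8 called as many genes as the real 13 (highest other 20, with screen 2 swapped).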

How the results depend on the processing

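All tests of alternatives were planned except those with the GC offset, with screens merged, summed or restricted to some libraries, with reassignment within GC classes, with the block and an estimated correlation together, and with screen 4 set against the screen 2 library, which were chosen after the result was seen. Reversals were counted only where a value past the threshold changed direction.

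Of the comparisons of the main results with an alternative, 106 stayed on the same side and within their limits, 45 moved and 1 passed anew. The mean agreement of the shRNA log2 ratios between screens (0.132 to 0.180 under alternatives) stayed within its spread. The 3 measures of complexity kept their direction under every alternative run, but with a screen left out or with sign flips their tests cannot pass, so these say nothing about the threshold. For the others the cause was not tested, except where screens were left out or merged, which leaves fewer samples.

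Against 0 shRNAs higher and 0 lower with edgeR, with 4745 at an unadjusted p under 0.05, DESeq2's size factors gave 89 and 5, the DESeq2 test 547 and 678, limma-voom 31 and 160, and the GC offset with the block 47 and 4. The GC offset alone gave 6 higher, no count filter 1, and summing the libraries before the drug in screens 3 and 4 gave 1. Leaving out a screen or a library gave 0 to 5 higher and 0 to 1 lower, with the most without screen 4. For genes, against 0 and 0 with 2286 at an unadjusted p under 0.05, the block gave 8 and 5, the DESeq2 test 365 and 274, the GC offset with the block 26 and 4, sums without the most abundant shRNA 8 and 1, and fry 2 and 13. Total counts alone gave 1 lower. Leaving out a screen or a library gave 0 to 13 higher and 0 to 5 lower, all from the fit without the screen 2 library after hygromycin. The block called 13 genes and the block with the GC offset 30, of which 10 were shared.

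The 72 genes with several shRNAs over the limit became 527 at a log2 ratio of 1, 11 at 3, 26 with a pseudocount of 5 CPM, 408 with TMM factors, 2071 in at least 1 screen, 17 with screens 1, 3 and 4 as 1, and 10 with screens 1 and 2 only. Leaving out a screen gave 11 to 43, with 11 without screen 1, 31 without screen 2, 43 without screen 3 and 28 without screen 4. Only the count of 5 in at least 3 screens passed the permutation test. The number of gene lists past the threshold went from 4 to 0 with an estimated correlation, and to 0 with it and the block, with or without the GC offset. The list of the earlier screen reversed with screens 1 and 2 only, at an adjusted p of 0.00225 (0.00225 to 0.677 over its alternatives). The BMP and TGF-β receptor list passed with the block at 0.0371 and with the GC offset and block at 0.0219 (0.0219 to 0.641 over its alternatives), both at the preset correlation. With the correlation estimated these were 0.281 and 0.239, and 0.629 without the block.

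For named genes, 918 of 954 comparisons stayed on their side of the threshold and 36 passed where the reported value did not, and 24 of the 954 had the other direction. For named shRNAs these numbers were 342 of 382, 40 and 14. For lists 176 of 195 stayed, 2 passed anew, 16 no longer passed and 1 reversed. For pairs of screens 22 of 24 correlations stayed and 2 moved.

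The 4125 shRNAs with 0 counts in all 8 libraries could not be assessed, whether for depth or because they were absent from the pool. Thinning the libraries to the smallest total left the complexity results on their side of the threshold. In simulated counts with the dispersion of the real ones, but with all libraries independent, the shRNA test found 0 of 50 at 4-fold and 23 of 50 at 64-fold.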

Other observations

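The gene and shRNA calls below were chosen after the result was seen, as was the set of libraries compared for the earlier fibroblast screen. With the screen as a block and the GC offset, the gene with the smallest adjusted p was Fbxo32, a muscle ubiquitin ligase, at 4.67 ± 0.71 (SE, n = 4 per group), followed by Tesc, a calcium-binding protein, at 4.98 ± 0.87 and Msl2l1 (now Msl2), a ubiquitin ligase of the MSL complex that acetylates histone H4, at 4.13 ± 0.75. Among the lower genes were Lbh, a transcriptional regulator of limb bud and heart, at −5.89 ± 1.11, and the ribosomal protein genes Rpl11 at −4.72 ± 0.96 and Rpl23a at −5.07 ± 1.09. Gemin5, which binds small nuclear RNAs in the complex of the survival motor neuron protein, gave 3.10 ± 0.73. None of these passed in edgeR's unblocked test of all 8 libraries with TMM scaling. Without the screen 2 library after hygromycin, the same edgeR test called Lbh, Rpl23a and Rpl11 lower (adjusted p = 0.02955, 0.02955 and 0.0485).

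A few shRNAs against the factors of the earlier fibroblast screen were abundant before hygromycin in screens 1 and 2, where 6 of 28 stood at least 5-fold above the library of screen 3 in each. Of the 28, 11 and 12 had under 10 CPM, as did most shRNAs of these libraries. The median over all shRNAs was 37 counts of 19106658 in screen 1 and 45 of 8749254 in screen 2. The 28 shRNAs together had a median log2 ratio of 0.00 between the libraries before the drug of screens 1 and 3, where all shRNAs had −1.38, and 19 of the 28 lay above that value, though only 13 had more CPM in screen 1 than in screen 3. Among the 6 in screen 1, the Pdpk1 shRNA CCGGGAATGAATATCTTAT had 17557 CPM in screen 1 and 29.5 in screen 3, the Nf1 shRNA GTAACAAGCCTTAAATTTA 5196 and 72.0, the Layn shRNA CTTGCTATAAAGTCATTTA 2026 and 43.1, and the Acvr1 shRNA CCCATTTGCACATAGAGAT 802 and 28.2. The hypothesis that GC content explains the higher median was tested against random sets with the same GC content. The median lay at percentile 99.57 of these sets, and at 99.9 for screens 2 and 3, which argues against GC content as the only reason. Between screens 1 and 2 it lay at 93.9 and between screens 4 and 3 at 54.7. How the pools of screens 1 and 2 were started is not stated, and no other reason was tested.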
